A study of Mus musculus with 48 samples.

How the data were processed

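RNA was measured by sequencing of total RNA, per the labels from mouse tumors in 44 libraries and from granule neuron precursors in 4, whose titles say tumor. The protocol also names tumorspheres. The 48 libraries were per the labels stranded and paired-end. The deposited files hold read counts per gene symbol, and per the labels the authors named CASAVA 1.7, STAR, BWA, HTSeq, limma and R 3.2.3 with the mouse genome build mm9, without stating the role of each tool, the annotation or the strand setting of the counter. Each file closes with 5 lines of reads assigned to no gene, in the form HTSeq writes. The values were checked to be whole numbers with a different total in each library. Of 34591 genes, Sox1 was absent from the files of set 1.

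Counts on genes ranged from 2687641 to 94733334 per library (median 29400000). Reads outside any gene made up 19.6% to 42.6% of the counted lines, unaligned reads 2.7% to 71.6% and ambiguous reads 0.438% to 2.26%. Reads carry no molecular identifiers in the files, so intervals and floors cover counting error only. Over 1128 pairs of libraries the lowest chi-square per degree of freedom was 7.91, and 0 pairs were identical.

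Groups followed the labels. The titles of all 8 Gfi1 OE libraries carry the replicate number 8, so that their numbers 1 to 8 were given here in the order of the titles. The 18 libraries of set 1 were fitted together with a term for line (14 residual degrees of freedom), and again with 6 group means for the effect within each line and for its difference between lines (12). In set 2 the libraries labelled Cas9 replicate 1 and Ezh2 KO + Ezh2 OE replicate 3 were left out, since the number in the title of each contradicts the number of its file, and the other 10 were fitted with 4 group means (6). The 6 control and 8 Gfi1 OE libraries were fitted together (12), as were the 4 libraries labelled WT GNP Myc Gfi1 and the 8 Gfi1 OE libraries (10). Set 1 and set 2 were kept apart because the titles of set 2 share a number that is not in set 1, taken as a possible batch. The titles of set 1 carry another number for each line, and the labels do not say what the numbers mean. The groups, comparisons, tests, gene lists, rule for named genes and most alternative settings were set before the data were examined.

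Each comparison used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, quasi-likelihood F-tests and Benjamini-Hochberg adjustment over all tested genes, and genes with an adjusted p under 0.05 are the called genes. The count test for single genes is therefore a model fitted across all genes. Log2 changes and their SE come from that model, and means and SDs per group from its normalised CPM. Against a group with 0 counts a fold was computed from a floor of 3 counts over the group, and against 1 to 3 counts a ratio with a 95% counting interval was given. A gene that was not called is described by its value alone.

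The 36 gene lists were the PRC2 and PRC1 subunits, Hox genes, developmental transcription factors, Gfi1 corepressors, Gfi1-repressed genes of blood cells, Sonic hedgehog pathway, Wnt readouts, Group 3 and Group 4 medulloblastoma markers, photoreceptor genes, granule neuron progenitor and maturing granule neuron genes, pan-neuronal, neural stem cell, Myc target, cell cycle, CDK inhibitor and p53 target genes, interferon and MHC class I genes, mesenchymal and matrix, hypoxia and immediate early genes, and markers of cortical and inhibitory neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, pericytes, meninges, choroid plexus, neutrophils, lymphocytes and red blood cells. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. A list of 11 MHC class II genes was written after the data were examined.

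Genes were named by a rule. It always took Ezh2, Gfi1, Gfi1b, Myc, Trp53, Cdkn2c and Cdkn2a where tested. It took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM in the higher group, an assigned symbol and no overlap between the libraries of the groups compared, and up to 4 called members of each list. Twist2, Lin28b and Igf2bp3 in the difference between lines, and the MHC class II genes outside the rule, were named after their values were seen. Genes are given by symbol, the only identifier in the files.

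Overlaps between called genes were tested with one-sided Fisher's exact tests against independent draws. Correlations of log2 changes were computed across genes. Genes called in set 1 were followed in set 2, with which set 1 shares no library.

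The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum of 1 CPM, each library left out in turn, a replicate block, other sets of libraries, host marker lists as covariates, and counts summed per line and arm. Group labels were also split in other ways. The tools were tested on simulated data with known changes, drawn with the spread that edgeR estimated, in a single run for each set of libraries. In that test 3.45% of edgeR's calls over 3 lines were genes without a change, and edgeR recovered 31% of 2-fold and 81% of 4-fold changes. Within lines it recovered at most 31% of 4-fold changes. For set 2 it recovered 38% of 2-fold and 77% of 4-fold changes with the knockout.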

Results

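RNA was sequenced from mouse tumors of a Myc-driven model of Group 3 medulloblastoma, a childhood tumor of the cerebellum, as 48 libraries in 13 groups. Per the labels the tumors came from tumorspheres, cells grown as floating clusters, that carried extra Myc and were placed in the cortex of immunodeficient mice. The labelled genotype is loss of p53 (Trp53) and p18 (Cdkn2c) in 44 libraries and wild-type in 4. Trp53 RNA was counted under both genotypes, in counts scaled to the library total (CPM) at 41.4 ± 3.94 (SD, n = 6) in the controls of line 19251 and 41.2 ± 4.84 (n = 4) in the libraries labelled wild-type, and so was Cdkn2c RNA, at 15.8 ± 7.8 and 13.3 ± 1.23 CPM. The first set held 3 tumor lines, 19251, 19554 and 19568, each with 3 Cas9 control libraries and 3 libraries with Ezh2 knocked out (Ezh2 KO). The second set held line 19568 alone, with 3 libraries each for Cas9, Ezh2 overexpression (Ezh2 OE), Ezh2 KO, and the knockout with Ezh2 put back (Ezh2 KO + Ezh2 OE, the rescue). This line differed from the other 2 in RNA of the Sonic hedgehog pathway. In Cas9 of set 1 it held 321 ± 35.9 CPM of Gli1, against 1.49 ± 0.95 in line 19251 and 8.81 ± 5.85 in line 19554 (n = 3 each). Myc measured 181 ± 54.8 CPM there, against 354 ± 366 and 801 ± 555. Cas9 replicates 1, 2 and 3 of line 19251 held 9.91, 738 and 314 CPM of Myc, and replicate 1 is doubted below. Line 19251 also had 6 control and 8 Gfi1 overexpression (Gfi1 OE) libraries, and 4 libraries were labelled WT GNP Myc Gfi1, for granule neuron progenitors of wild-type mice. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which marks silenced genes, and Gfi1 is a transcriptional repressor that the series title relates to loss of Ezh2. Counts on genes ranged from 2687641 to 94733334 per library, with a median of 29400000, and the files name genes by symbol only. The labels do not state that replicates are separate animals.

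Ezh2 RNA averaged 62.0 ± 19.3 CPM (SD, n = 3) in Ezh2 KO and 64.5 ± 28.6 in Cas9 of line 19251 (32.8, 88.2 and 72.6 in Cas9 replicates 1, 2 and 3), 74.1 ± 7.62 and 75.2 ± 9.80 in line 19554, and 43.7 ± 5.38 and 74.5 ± 7.98 in line 19568 of set 1. In set 2, Ezh2 measured 51.3 ± 4.45 CPM in Ezh2 KO, 91.9 and 93.5 in Cas9 replicates 2 and 3, 2140 ± 367 in Ezh2 OE, and 5040 and 6580 in rescue replicates 1 and 2. The library labelled Cas9 set 2 replicate 1 held 5130 CPM of Ezh2 and the library labelled rescue replicate 3 held 101. Both were left out of the set 2 comparisons because their title and file numbers contradict each other. The knockout was made with Cas9, so that a gene-level count does not show whether the reading frame was broken. Gfi1 RNA measured 225 ± 157 CPM (n = 8) with Gfi1 OE, 0.125 ± 0.0923 (n = 6) in its controls, and 0.471 ± 0.254 (n = 4) in the libraries labelled WT GNP Myc Gfi1. In the 3 Ezh2 KO groups of set 1 Gfi1 measured 1.64 ± 0.297, 0.406 ± 0.121 and 0.897 ± 0.301 CPM in lines 19251, 19554 and 19568 (n = 3 each). Their Cas9 groups held 0.441 ± 0.439, 0.0878 ± 0.127 and 0.281 ± 0.441 CPM. The libraries of the 2 arms overlapped in line 19568 (0.55 to 1.09 against 0 to 0.789) and not in the other lines.

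**Figure D1:**
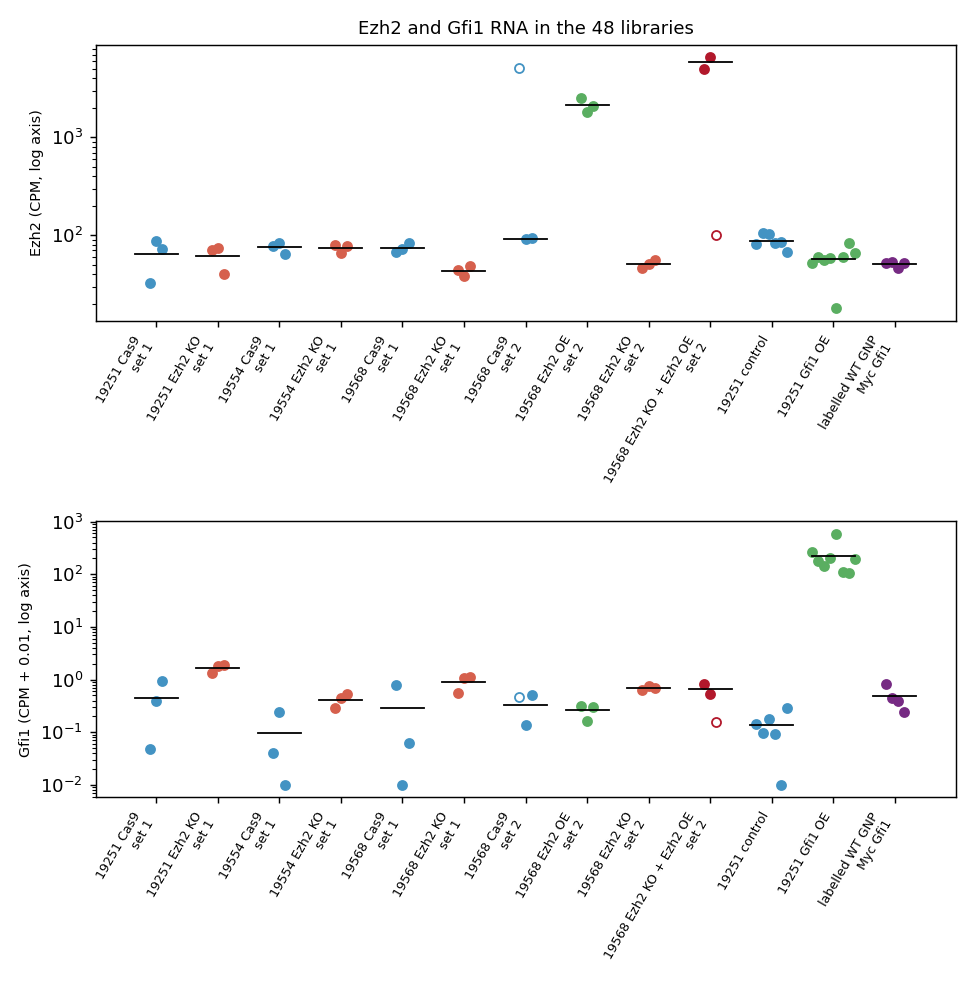
Ezh2 (CPM, log axis) and Gfi1 (CPM + 0.01, log axis) in each of the 48 libraries, by group; points are libraries, black bars are group means without the 2 open circles, which mark the libraries left out of the set 2 comparisons. Gfi1 lay between 107 and 592 CPM in the 8 Gfi1 OE libraries and between 0.232 and 0.83 CPM in the 4 libraries labelled WT GNP Myc Gfi1.

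The comparison of Ezh2 KO with Cas9 over the 3 lines of set 1 asked which genes changed with loss of Ezh2. Gata4, a transcription factor of heart and endoderm development, rose by a log2 change of 6.19 (SE 0.54, adjusted p 3.45e-05), from 0.0619 ± 0.0798 to 4.15 ± 1.49 CPM (SD, n = 9 each). Hox genes, which set position along the body axis and are known PRC2 targets, rose in the same tumors. Among them Hoxb13 rose by 6.95 (SE 1.18, adjusted p 0.0128), from 0.199 ± 0.571 to 10.1 ± 3.95 CPM, and Hoxd13 by 6.36 (SE 1.28, adjusted p 0.0381), from 2.70 ± 5.78 to 29.4 ± 19 CPM. Igf2bp1, an RNA-binding protein of fetal tissue, rose by 5.95 (SE 1.04, adjusted p 0.0153), from 2.74 ± 6.90 to 46.9 ± 39.8 CPM. Gfi1 showed a log2 change of 1.77 (SE 0.60, unadjusted edgeR p 0.00946, adjusted p 0.371), from 0.268 ± 0.352 to 0.946 ± 0.53 CPM, and did not pass the threshold. With limma-voom Gfi1 measured 2.61 (adjusted p 0.0484), and over the other settings its adjusted p lay between 0.0881 and 0.969. Ezh2 itself showed -0.31 (SE 0.17, adjusted p 0.699).

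In all, 68 of 16461 genes passed an adjusted p of 0.05 in edgeR, 61 higher and 7 lower, and 1326 had an unadjusted p under 0.05. Of 29 tested Hox genes 20 rose, 0 fell and 9 were not called, with 21 rising when adjusted over the list alone. Their median log2 change was 5.19 (camera adjusted p 1.87e-70, and 0.000704 with an estimated correlation). Hoxd8 (6.15), Hoxb9 (6.05), Hoxb7 (5.97), Hoxb2 (5.79), Hoxc4 (5.63), Hoxc9 (5.53) and Hoxb3 (5.34) were among them. Of 56 developmental transcription factors 8 rose and 0 fell, with 17 rising when adjusted over the list alone (camera adjusted p 4.27e-30, and 0.000342 with an estimated correlation). They included Hand2 of heart and limb (log2 change 5.05), Vax2 of the eye (4.63) and Tbx18 (2.14). Lmx1a, in the Group 4 medulloblastoma list for its role in the rhombic lip, rose by 3.24.

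The 7 genes that fell did so by less than 1 log2 unit. They included Gpx4, which repairs oxidised membrane lipids (-0.62, SE 0.11, adjusted p 0.0172), Gclm of glutathione synthesis (-0.60), Gne of sialic acid synthesis (-0.67), Rrm2b, a p53-regulated ribonucleotide reductase subunit (-0.58), Spata2 (-0.86) and Tmem64 (-0.44). Rrm2b was the 1 called member of 24 tested p53 targets. Among 18 PRC1 subunits 0 were called over all genes and 5 rose when adjusted over the list alone (camera adjusted p 0.0193, and 0.0674 with an estimated correlation). Of 29 cell cycle genes 25 had a positive change (9 without 19251 Cas9 replicate 1) and 0 were called (camera adjusted p 0.00772, and 0.943 with an estimated correlation). All 26 interferon and MHC class I genes had a negative change, with a median of -0.73, and 0 were called (camera adjusted p 0.124). That direction rested on 19251 Cas9 replicate 3, without which 22 were positive and the median was 0.359. Of the 10 Wnt readouts and 23 mesenchymal and matrix genes 0 were called over all genes, and every other list of at least 5 tested genes had 0 called. The other tools called 131 genes (limma-voom) and 289 (DESeq2) in this comparison, and edgeR called 215 without 19251 Cas9 replicate 1, a library with 9.91 CPM of Myc, 456 CPM of the myelin gene Mbp, 520 CPM of Xist and 0.0378 CPM of the Y-linked gene Ddx3y. The other 2 Cas9 libraries of the line held 13.5 and 66.1 CPM of Xist and 30.8 and 84.9 of Ddx3y. Cell cycle genes averaged 1.73 on a log2(CPM + 1) scale in replicate 1, against 7.23 and 6.81 in those 2. These values argue against tumor RNA of line 19251 as the main content of replicate 1. That library stayed in the fits because the groups were set before the data were examined. Counts summed per line and arm gave 0 calls in edgeR with 3 sums against 3, and 962 genes at an unadjusted p under 0.05.

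**Figure D2:**
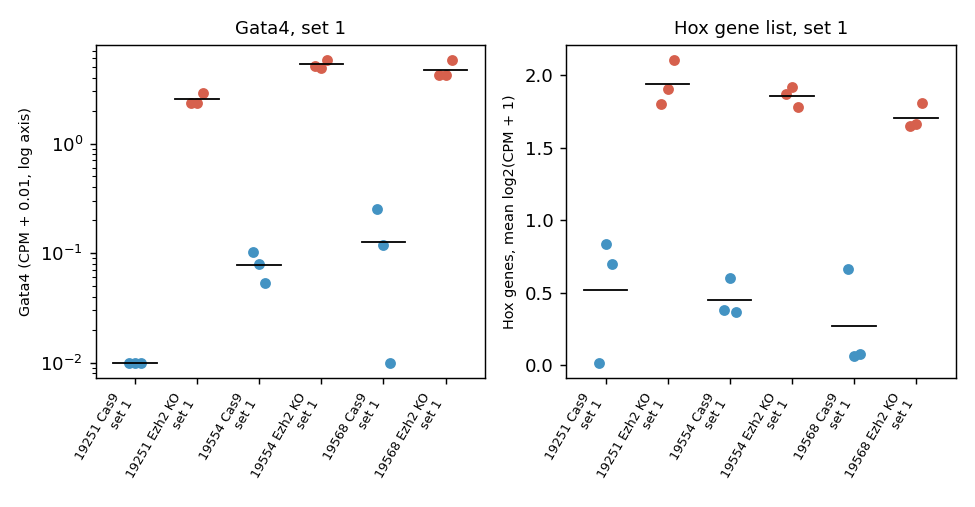
Gata4 (CPM + 0.01, log axis) and the mean of the Hox gene list (log2(CPM + 1)) in the 18 libraries of set 1; points are libraries and black bars group means. Gata4 measured 2.32 to 2.90 CPM in the Ezh2 KO libraries of line 19251, 4.87 to 5.80 in line 19554 and 4.18 to 5.73 in line 19568, and at most 0.24 in the 9 Cas9 libraries.

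Within single lines of set 1, Gata4, the motor neuron factor Mnx1 and the blood stem cell factor Tal1 rose with Ezh2 KO in all 3 lines. In line 19251 Gata4 rose to 2.34 ± 0.268 CPM (n = 3) from 0 counts, at least 74.1-fold over a floor of 3 counts in the group (adjusted p 0.00236). Hoxc4 rose at least 184-fold, Hoxc13 at least 109-fold, Hoxd3 at least 100-fold, Hoxb5 at least 72.8-fold and Hand2 at least 73.5-fold in that line. In line 19554 Hoxd13 rose by 9.30 on the log2 scale (SE 1.17, adjusted p 0.00217), from 0.0682 ± 0.0826 to 50.1 ± 13.2 CPM, and Igf2bp1 by 9.57 (SE 1.44, adjusted p 0.00736). Hoxa11 was 1000-fold higher there (95% counting interval 277 to 8260), Hoxb13 1120-fold (201 to 44300), Hoxd8 983-fold (272 to 8130) and Hoxa10 832-fold (284 to 4040). In line 19568 the 5 called genes all rose, namely Hoxa11as (381-fold, 68.2 to 15100), Gata4 (log2 change 5.21, SE 0.72), Msx3 (4.71), Mnx1 (3.79) and Tal1 (3.66), each at adjusted p 0.0495. Gfi1 measured 1.75, 2.07 and 1.56 in lines 19251, 19554 and 19568 (adjusted p 0.438, 0.688 and 1). The strand used in counting is not stated, so that reads of Hoxa11 and its antisense gene Hoxa11as cannot be separated with certainty.

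Of 18514 genes tested, edgeR called 48 in line 19251 (45 higher, 3 lower), 89 in line 19554 (84 higher, 5 lower) and 5 in line 19568 (5 higher, 0 lower). Unadjusted p-values under 0.05 numbered 3141, 1726 and 580. The genes that fell included Cntnap1 of the node of Ranvier (-3.42), Smcr8 (-1.04) and the transcription factor Foxo3 (-0.99) in line 19251, and Rtn4r, the Nogo receptor (-3.02), Snx7 (-1.52) and Dazap2 (-0.89) in line 19554. Hox genes that rose numbered 14 of 35 in line 19251, 13 in line 19554 and 0 in line 19568. Adjusted over the list alone, 30 rose in line 19568 (camera adjusted p 0.00128 with an estimated correlation, against 0.0502 in line 19251 and 0.0323 in line 19554). Lines 19251 and 19554 shared 24 higher genes where 0.204 would be shared by independent draws (Fisher's exact test, one-sided p 5.43e-46). Line 19568 shared 3 with line 19251 (0.0122, p 1.34e-07) and 4 with line 19554 (0.0227, p 1.96e-09), and genes are not independent replicates.

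A test of the difference between lines called 3 genes in edgeR (1798 at an unadjusted p under 0.05), chosen for naming after their values were seen. Twist2, a mesenchymal transcription factor, rose in lines 19251 (log2 change 6.17, SE 0.60) and 19554 (8.81, SE 0.72) and measured -0.49 (SE 0.44) in line 19568, whose Cas9 libraries already held 41.0 ± 10.1 CPM (adjusted p of the difference 0.000631). Igf2bp3, a fetal RNA-binding protein, measured 6.11, 7.52 and 0.71 (adjusted p 0.0123). Its Cas9 libraries held 0.945 ± 0.72, 0.502 ± 0.227 and 49.7 ± 23.7 CPM in lines 19251, 19554 and 19568. Lin28b, which blocks let-7 microRNA processing, measured -0.13 in line 19251, 7.87 in line 19554 and 0.00 in line 19568 (adjusted p 0.00125). It went from 0.327 ± 0.142 to 77.5 ± 29.6 CPM in line 19554 (n = 3 each). The Cas9 libraries of lines 19251 and 19568 already held 46 ± 34.8 and 33.2 ± 6.93 CPM of Lin28b. In the 6 controls of line 19251 it ranged from 1.84 to 117 CPM. The count of 3 genes was 20 without 19251 Cas9 replicate 1 and 5 without its replicate 2. It was 10 and 8 without 19554 Cas9 replicates 1 and 2.

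The counts within lines moved when single libraries were left out. In line 19251 the count was 79 and 375 without its Cas9 replicates 1 and 2, 30, 26 and 30 without its Ezh2 KO replicates 1, 2 and 3, 86 without 19554 Cas9 replicate 3, and 30, 30 and 29 without the 3 Ezh2 KO libraries of line 19568. In line 19554 it was 400, 150 and 155 without 19251 Cas9 replicates 1, 2 and 3, 56 without 19251 Ezh2 KO replicate 1, 29 without its own Cas9 replicate 1, 48 and 45 without its Ezh2 KO replicates 1 and 2, and 54, 59 and 50 without the Ezh2 KO libraries of line 19568. In line 19568 it was 20 without 19251 Cas9 replicate 1 and 18 without its own Cas9 replicate 1. It was 1 without 19554 Cas9 replicate 1 or 3 or 19568 Cas9 replicate 3, and 0 without any of 19251 Cas9 replicate 2, 19554 Cas9 replicate 2, 19568 Cas9 replicate 2 or the 9 Ezh2 KO libraries. The called genes of line 19568 numbered 179 when its 6 libraries were fitted alone and 250 with a replicate block. The 6 libraries of line 19251 alone gave 0 in edgeR (831 unadjusted) and those of line 19554 gave 29.

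Line 19568 of set 2 gave a test of Ezh2 KO against Cas9 in other libraries of a line of set 1 (3 libraries against 2). Ezh2 fell to 49.5 ± 2.48 from 95.7 ± 7.06 normalised CPM (log2 change -0.95, SE 0.13, adjusted p 0.00416). Cdkn1c, the imprinted cell cycle inhibitor p57, rose by 4.71 (SE 0.76, adjusted p 0.00688), from 17.2 ± 11.9 to 439 ± 69.3 CPM. Sfrp1, a secreted Wnt inhibitor, rose by 4.73 (SE 0.26, adjusted p 4.25e-05), from 1.87 ± 0.309 to 50.6 ± 3.79 CPM. Gata4 rose by 6.53 (SE 1.07, adjusted p 0.00754), Hoxb13 454-fold (95% counting interval 81.3 to 18000) and Hoxa6 at least 28.6-fold. MHC class II genes, which present antigen to T cells, fell, with H2-Eb2 at -6.05 (SE 0.28, adjusted p 1.61e-05) and H2-Aa at -4.56 (adjusted p 2.44e-06), where reads of the H2-E paralogs may not be separable. Gfi1 showed 0.83 (SE 0.54, unadjusted p 0.156, adjusted p 0.392), at 0.659 ± 0.0366 against 0.338 ± 0.299 CPM, and did not pass the threshold.

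Of 34 tested Hox genes 32 rose, 0 fell and 2 were not called, and 33 rose when adjusted over the list alone. Their median log2 change was 5.23, or 4.89 with genes absent from Cas9 set at their bound (camera adjusted p 2.23e-38, and 0.0714 with an estimated correlation). Of 67 developmental transcription factors 23 rose and 0 fell, or 42 and 3 adjusted over the list alone, with Pitx1 of the hindlimb 205-fold higher (36.5 to 8100), Lhx9 at 4.27, Vax2 at 3.85 and Gata6 at 3.26 (camera adjusted p 1.94e-14, and 0.189 with an estimated correlation). Of 18 PRC1 subunits 6 rose, among them Cbx8 (1.21), Cbx2 (0.93), Bmi1 (0.53) and Phc1 (0.44), and 9 when adjusted over the list alone (camera adjusted p 0.0109, and 0.578 with an estimated correlation). Of 9 granule neuron progenitor genes 3 rose, namely Lhx9, Pax6 (2.29) and Mfap4 (1.5), and 5 adjusted over the list alone (camera adjusted p 0.00152, and 0.394 with an estimated correlation). In the Sonic hedgehog list Sfrp1, Smo (0.43) and Ccnd1 (0.71) rose and the receptor Boc fell (-1.16), among 11 tested (camera adjusted p 0.0109, and 0.564 with an estimated correlation). Of 10 Wnt readouts Nkd1 (2.28) and Lef1 (2.29) rose, and 4 adjusted over the list alone (camera adjusted p 0.00993, and 0.564 with an estimated correlation).

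Among 26 interferon and MHC class I genes 0 had a positive change, and Bst2 (-1.84) and H2-K1 (-1.48) fell (camera adjusted p 0.000502, and 0.949 with an estimated correlation). The pan-neuronal list had 3 of 21 positive changes (14 without Cas9 replicate 2) and 0 called. Of 23 mesenchymal and matrix genes 4 rose, namely Mmp14 (1.11), Tgfbi (1.19), Lamb1 (0.78) and Col6a1 (0.89). Single genes of other cell types were called as well, among them Tmem119 of microglia (1.97), Cdh5 of endothelium (0.86), Myh11 (3.91) and Tagln (-2.85) of smooth muscle and Ogn of meninges (-2.52), while the microglia list as a whole had a median of -0.49. The largest falls outside the lists were Sds, a serine dehydratase (350-fold lower, 119 to 1700), Tbx10 (285-fold, 78.1 to 2360), Cerkl (-6.46), Edn2 (-5.85), Krt17 (47.3-fold, 15.6 to 234), Cytl1 (-5.37) and Anxa8 (-5.14), and Prss34, a mast cell protease, rose at least 37.9-fold. Id2 fell by 1.85 and the Notch modifier Lfng by 2.75 on the log2 scale.

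In all, 1609 of 17663 genes were called in set 2, 1039 higher and 570 lower. That number moved widely with the libraries taken, the filter and a replicate block, as given further below. The count was 380 and 237 without Cas9 replicates 2 and 3, 1024, 653 and 805 without Ezh2 KO replicates 1, 2 and 3, and 232 without the libraries rich in satellite-like counts. Where this left 1 Cas9 library, it was assumed to vary like the libraries of the other groups. The genes chosen in set 1 shared no library with these. All 61 genes that rose over the 3 lines had a positive change in set 2, with a median of 3.59, and 48 of them rose (camera p 0.000467 with an estimated correlation). All 7 genes that had fallen were negative, with a median of -0.51, and 2 fell.

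In the rescue, Ezh2 rose to 5856 ± 1144 from 49.5 ± 2.48 CPM in the knockout (log2 change 6.89, SE 0.16, adjusted p 1.56e-07, 2 libraries against 3). Gfi1 measured 0.005 (adjusted p 0.998), or -0.05 with limma-voom. MHC class II genes rose, with H2-Aa going from 12 ± 1.51 to 182 ± 4.27 CPM (3.92, SE 0.15, adjusted p 5.18e-06), H2-Eb1 at 3.52 and H2-Eb2 at 5.59. The homeobox genes Pitx1 (-4.47, SE 0.72, adjusted p 0.0249), Uncx (-4.46) and Tlx1 (-4.10) fell, as did Hoxa11as (-4.71), while the homeobox gene Meox2 rose (3.66). Prss34 fell 64.8-fold (17.7 to 539), the germ cell gene Tex14 by 5.21 on the log2 scale, Ccdc162 by 4.65 and Myh11 by 3.32. The matrix genes Col6a4 (5.23) and Ogn (3.36), the smooth muscle actin Actg2 (4.13) and the actin-severing protein Scin (3.49) rose.

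Of 34 Hox genes 0 rose and 5 fell in the rescue, with 26 falling when adjusted over the list alone and a median of -2.47 (camera adjusted p 1.34e-29, and 0.136 with an estimated correlation). Hoxc11 (-3.18), Hoxd10 (-3.15), Hoxb13 (-2.72) and Hoxd8 (-2.27) were among the 5. Of the developmental factors Pitx1, Uncx and Irx2 (-1.84) fell and Meox2 rose, among 67 tested (camera adjusted p 0.00105, and 0.76 with an estimated correlation). Of 18 PRC1 subunits Bmi1 (-0.61) and Cbx2 (-1.17) fell. Among 36 Myc targets 1 was positive, 0 were called over all genes and 17 fell when adjusted over the list alone (camera adjusted p 1.77e-10, and 0.76 with an estimated correlation). All 29 cell cycle genes were negative and 0 were called (camera adjusted p 7.37e-08, and 0.76 with an estimated correlation). Bst2 rose (2.02) among 26 interferon genes, 23 of them positive (camera adjusted p 0.00583, and 0.953 with an estimated correlation). Beside these, all 15 microglia and macrophage markers had positive changes with 0 called (median 0.76, camera adjusted p 0.00051, and 0.76 with an estimated correlation), as had all 11 endothelial markers, of which Cdh5 rose (1.03; camera adjusted p 0.000789, and 0.76 with an estimated correlation).

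The 5 genes raised by Ezh2 KO in line 19568 of set 1 all rose with the knockout in set 2 (median 4.75) and all had a negative change in the rescue, with a median of -2.32 (range -2.58 to -2.10 over refits without single libraries). Of these 5, 2 fell (camera p 0.00533 with an estimated correlation), and against Cas9 the rescue lay at a median of 2.44, with 3 genes higher. Over the 140 genes raised in a fit of the 6 libraries of line 19568 in set 1 alone, a choice made after seeing the data, the median in the rescue was -0.27, with 97 negative and 43 positive. Of the 61 genes raised over 3 lines, 53 had a negative change in the rescue (median -1.16) and 7 fell (camera p 0.00461 with an estimated correlation). Against Cas9 their median was 2.11, with 31 higher (camera p 0.00228 with an estimated correlation). The 7 genes lowered in set 1 had a median of 0.0654 in the rescue and 0 were called. Of the 1039 genes raised by the knockout of set 2 itself (median 1.08), 50 fell and 7 rose further in the rescue, with a median of -0.171, and of the 570 lowered (median -0.793), 44 rose and 1 fell further, with a median of 0.26. Both comparisons share the knockout libraries of set 2, so that some opposite signs are expected by chance.

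**Figure D3:**
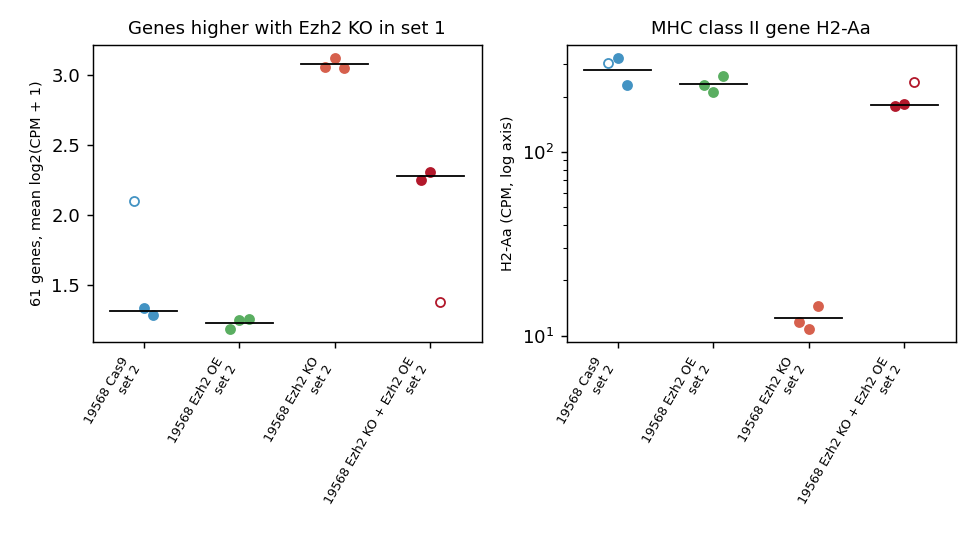
Mean log2(CPM + 1) of the 61 genes raised by Ezh2 KO in set 1, and CPM of H2-Aa (log axis), in the 12 libraries of set 2; points are libraries, black bars group means without the 2 open circles, which mark the libraries left out. The 61 genes averaged 3.05 to 3.12 in Ezh2 KO, 2.25 and 2.31 in the rescue and 1.29 and 1.34 in Cas9, and H2-Aa lay between 10.9 and 14.5 CPM in Ezh2 KO.

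The rescue differed from its knockout at 213 of 17663 genes, 137 higher and 76 lower (3284 at an unadjusted p under 0.05). That count was 58 and 21 without rescue replicates 1 and 2, the latter carrying a description that names another arm, 130 and 118 without Cas9 replicates 2 and 3, 704 and 374 without Ezh2 OE replicates 1 and 3, 62, 31 and 60 without Ezh2 KO replicates 1, 2 and 3, and 1058 with DESeq2. A single library left in the rescue or in Cas9 was assumed to vary like those of the other groups. Against Cas9 the rescue differed at 1375 genes, 907 higher and 468 lower (4221 unadjusted). That count moved widely with the libraries taken, the tool, the filter and a replicate block, as given further below. Tex13 was 558-fold higher (99.9 to 22100), Gcg, the glucagon gene, 56.2-fold (15.2 to 469), Hoxb2 rose by 5.95 and Nkx2-9 by 5.13, while Cerkl (-6.23), Sds (-5.57), Mpzl2 (-4.46) and Kcnip1 (-4.11) fell. Of 34 Hox genes 12 were higher than in Cas9, 17 adjusted over the list alone (camera adjusted p 9.18e-16, and 0.561 with an estimated correlation). Of 36 Myc targets 8 fell, such as Wdr43 (-0.79) and Nop56 (-0.56) (camera adjusted p 5.71e-08, and 0.717 with an estimated correlation). Of 29 cell cycle genes Ccnb2 (-1.75), Cenpe (-0.66), Kif11 (-0.63) and Ccnb1 (-0.49) fell. Mesenchymal genes rose at 6 of 23, with Mmp14 at 1.68, and Cdkn1c stayed higher at 3.93. The count was 399 and 404 without rescue replicates 1 and 2, 243 and 113 without Cas9 replicates 2 and 3, 2134 without Ezh2 OE replicate 1 and 831 without Ezh2 KO replicate 2.

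Overexpression of Ezh2 without the knockout raised Ezh2 from 95.7 ± 7.06 to 2151 ± 173 CPM (log2 change 4.49, SE 0.17, adjusted p 1.07e-05, 3 libraries against 2). Ezh2 was the 1 gene called of 17663 by edgeR, and 498 genes had an unadjusted p under 0.05. More genes were called without the low-count filter, and none with all libraries as labelled, as given further below. Hox genes had a positive change at 7 of 34 (13 without Cas9 replicate 3, where 16 were negative) and 0 were called (camera adjusted p 0.000782, and 0.984 with an estimated correlation). The 61 genes raised by Ezh2 KO in set 1 had a negative change at 45 and 0 were called, with a median of -0.44 (camera p 0.0625 with an estimated correlation). MHC class II genes had 0 calls.

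Gfi1 OE in line 19251 raised Gfi1 by 11.14 on the log2 scale (SE 0.74, adjusted p 4.02e-07), from 0.115 ± 0.0789 (n = 6) to 250 ± 227 CPM (n = 8). Among the largest rises were Msln, a surface protein of mesothelium (8.89, SE 0.40, adjusted p 9.99e-09, from 0.116 ± 0.0926 to 49.4 ± 14.8 CPM), the tight junction gene Cldn4 (2590-fold, 95% counting interval 465 to 103000), the keratin Krt23 (1280-fold, 229 to 50500) and Pof1b (8.60). Cd79a, of the B cell receptor, rose by 6.90 (SE 0.36, adjusted p 3.96e-08), from 0.238 ± 0.114 to 28.5 ± 8.50 CPM. Sox2 fell by 3.75 (SE 0.49, adjusted p 8.85e-05), from 53.3 ± 44.8 to 3.92 ± 1.68 CPM, and Nfib (-3.74), Meis1 (-4.57) and Pax3 (-5.60) fell as well. Myc fell by 0.73 (SE 0.24, adjusted p 0.0361), from 899 ± 330 to 541 ± 142 CPM.

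Of 17024 genes 4187 were called, 1891 higher and 2296 lower (6220 unadjusted). Of 17 tested genes that Gfi1 represses in blood cells 0 rose and 7 fell, 7 also when adjusted over the list alone, among them Meis1, Id2 (-1.88) and Egr1 (-2.26) (camera adjusted p 0.00815, and 0.505 with an estimated correlation). Of 17 neural stem cell genes 0 rose and 9 fell, 11 adjusted over the list alone, with Vim (-2.44), Msi1 (-3.05) and Id3 (-1.47) beside Sox2 (camera adjusted p 0.00657, and 0.975 with an estimated correlation). Of 13 hypoxia genes 6 fell, 8 adjusted over the list alone, with Egln3 at -4.02 and Adm at -2.77 (camera adjusted p 0.0123, and 0.975 with an estimated correlation). Of 12 immediate early genes Fos (-2.75), Atf3 (-1.37), Egr1 and Jun (-0.81) fell (camera adjusted p 0.0484, and 0.975 with an estimated correlation). Of 11 PRC2 subunits 4 fell, namely Phf19 (-2.36), Rbbp7 (-0.55), Rbbp4 (-0.45) and Eed (-0.45), and Ezh2 measured -0.53 (SE 0.20, adjusted p 0.071). PRC1 subunits went both ways, with Cbx7 (1.53) and Pcgf6 (0.54) among 4 that rose and Phc1 (-0.68) among 3 that fell.

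Developmental factors likewise went both ways, 9 up and 15 down of 52, with Foxc2 (5.05) and Barx2 (4.61) higher and Pax3 and Irx5 (-2.13) lower. Of 6 tested Hox genes 4 fell, Hoxa2 at -5.93 and Hoxa3 at -4.75. Of 11 genes of the Sonic hedgehog list 0 rose and 4 fell, namely Gli3 (-4.01), Boc (-3.15), Ccnd1 (-1.42) and Smo (-0.85), the same numbers when adjusted over the list alone (camera adjusted p 0.234, and 0.975 with an estimated correlation). Of 13 granule neuron progenitor genes 2 rose and 5 fell, among them Zic2 (1.15), Pax6 (-3.37), Barhl1 (-3.80) and Zic1 (-1.75). Of 12 corepressors that Gfi1 recruits Rcor3 rose (0.65) and Jub (-1.39) and Kdm1a (-0.49) fell. Of 10 Wnt readouts 3 rose, among them the antagonist Notum (4.44) and Nkd1 (1.7), and 3 fell, among them Apcdd1 (-1.82). Further rises were Crh, a stress hormone (498-fold, 138 to 4120), the pre-B cell gene Igll1 (503-fold, 139 to 4150) and Inhbe (at least 59.5-fold). Crabp1, which binds retinoic acid, was 14600-fold lower by pooled counts (2610 to 575000). Its log2 change in the model was -12.24 (SE 1.47), from 32.3 ± 61.5 CPM in the 6 controls, a spread that the counting interval does not cover. Further falls were Mybpc1 (-8.64), Srpx (-6.10), Piwil2 (-5.81), Epha3 (-5.54), Gem (-5.17) and En1 (-4.66). Trp53 fell by 0.44. Markers of other cells moved beside them. Of 10 astrocyte markers S100b (1.63) rose and 3 fell, among them Slc1a3 (-1.71), and of 8 pericyte and smooth muscle markers 2 rose, among them Abcc9 (2.19), and Acta2 (-3.61) fell. Of 6 meningeal markers Slc6a13 (3.97) and Igf2 (3.30) rose, of 6 oligodendrocyte precursor markers Olig2 (-3.27) and Pdgfra (-1.47) fell, and of 8 inhibitory neuron markers Vip (6.42) rose and Pvalb (-4.55) fell. With host marker lists as covariates the count was 2214. It was 5738 without Gfi1 OE replicate 5, in which 23.5% of counts fell on 2 satellite-like genes. The endothelial list had 11 of 11 positive changes and 0 called, and the Group 4, photoreceptor, CDK inhibitor, oligodendrocyte, microglia, choroid plexus, red blood cell and neutrophil lists had 0 called.

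The effect of Ezh2 KO and that of Gfi1 OE were set side by side within line 19251, where they share no library. Over 16765 genes Spearman's rho between the log2 changes was -0.0199 and Pearson's r -0.0485, across genes, which are not independent replicates. Ezh2 KO raised 45 genes, of which 18 were tested in both, as the low-count filter of the Gfi1 comparison left out the others. Of the 18, 3 also rose with Gfi1 OE (1.87 for independent draws, one-sided Fisher's exact p 0.287), namely Tal1, Nkx2-4 and C130021I20Rik, and 2 fell (2.46), namely Chchd7 and Lrrc17. The overlap does not cover the genes left out. Gata4, raised by Ezh2 KO, measured 0 to 0.744 CPM in the 8 Gfi1 OE libraries. With the knockout of set 2, 217 genes were higher there and lower with Gfi1 OE (127 for independent draws, p 9.97e-17) and 84 were higher in both (93.5, p 0.869). Of the genes lowered by that knockout 100 were higher with Gfi1 OE (53.7, p 4.95e-10) and 69 lower (72.7, p 0.704). The knockout-raised genes of set 2 had a median of -0.26 with Gfi1 OE (camera p 0.0103, and 0.323 with an estimated correlation), and the knockout-lowered genes one of -0.00537 (camera p 0.349, and 0.715 with an estimated correlation). That pair crossed lines 19568 and 19251.

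The 4 libraries labelled WT GNP Myc Gfi1 were compared with the 8 Gfi1 OE libraries of line 19251, 2 groups that differ in the labels by genotype and cell of origin together. The title numbers differ between the 2 groups as well, and also between single libraries, and the labels name no batch. A batch could not be told apart from the groups here. Across genes, which are not independent replicates, these 4 libraries had a mean correlation of 0.705 with Ezh2 KO of line 19568 in set 2 and -0.412 with Gfi1 OE. Gfi1 was lower in the former by 9.06 on the log2 scale (-9.06, SE 0.82, adjusted p 2.25e-06), at 0.460 ± 0.248 against 243 ± 215 CPM. Cdkn1c rose by 7.24 (SE 0.55, adjusted p 7.27e-07), to 1194 ± 127 from 8.38 ± 6.83 CPM, and Igf2, an imprinted growth factor, by 5.29. Cdkn1c, and Sfrp1 and Hox genes given below, had also risen with Ezh2 KO of line 19568 in set 2. Genes of the Sonic hedgehog list were higher, with 10 of 12 members up and 1 down, among them Sfrp1 (6.56), Gli3 (2.96), Ccnd1 (2.65) and Gli2 (1.32) (camera adjusted p 0.000672, and 0.605 with an estimated correlation). Myc was lower by 1.20 (-1.20, SE 0.23, adjusted p 0.000997).

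In all 8413 of 17278 genes were called, 3777 higher and 4636 lower (9635 unadjusted). Of 24 Hox genes 17 rose and 2 fell, 18 and 3 adjusted over the list alone, with Hoxd13 at 8.37 and Hoxa10 1030-fold higher (285 to 8560) (camera adjusted p 0.000314, and 0.708 with an estimated correlation). All 6 oligodendrocyte precursor markers rose, including Cspg4 (3.91) and Pdgfra (2.26) (camera adjusted p 0.000813, and 0.605 with an estimated correlation). Of 21 pan-neuronal genes 0 rose and 13 fell, 14 adjusted over the list alone, with Ina at -4.39 and Elavl3 at -3.85 (camera adjusted p 0.000314, and 0.605 with an estimated correlation). Of 13 granule neuron progenitor genes 1 rose and 8 fell, among them Zic1 (-3.77) and Nhlh1, at least 270-fold lower (camera adjusted p 0.0423, and 0.605 with an estimated correlation). Of 23 mesenchymal genes 11 rose and 1 fell, with Mmp2 at 5.56 and Cdh2 at -2.71 (camera adjusted p 0.0173, and 0.605 with an estimated correlation). Of 26 interferon genes 3 rose and 11 fell. The largest rises included the odorant receptor Olfr368 (at least 709-fold), Gpx2 (10.25), Nkx2-3 (1290-fold, 355 to 10700), Fat2 (9.34) and Sp7 of bone (8.79), and the largest falls included Prom2 (3070-fold, 551 to 121000) and Cldn3 (at least 620-fold).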

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

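The tests by genes private to a line, of crossed labels, of an Ezh2 construct in a Cas9 tumor by 2 measures, of microglia and macrophages, of lymphocytes and of MHC class II genes in set 1 were chosen only after the result was seen.

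Single libraries lay far from the others of their group in 13 of 41 tested sets of values. Most of these 13 came from Gfi1 OE replicate 5 and were not independent of each other. Only the controls and Gfi1 OE of line 19251 and the libraries labelled WT GNP Myc Gfi1 were tested, and no group of 3 libraries was. Gfi1 OE replicate 5 held 23.5% of its counts on 2 satellite-like genes (0.013% to 0.11% in the other 7), 0.393% mitochondrial counts (6.6% to 7.81%) and 71.6% unaligned reads (3.28% to 8.25%). In that library Ezh2 measured 17.9 CPM (52.7 to 84), Gfi1 592 (107 to 264), Trp53 16 (26.1 to 34.5), Cdkn2c 20.8 (6.53 to 11.1), Cdkn2a 109 (34 to 48) and Gata4 0.744 (0 to 0.148). Gfi1 OE replicate 7 held 237 CPM of Gli1 (3.14 to 65.9) and 468 of Ptch1 (56.9 to 74.8). In line 19251, control replicate 3 held 47 CPM of Gli1 (0.563 to 3.7) and control replicate 5 held 106 CPM of Cdkn2a (32.5 to 56.5). No explanation was tested for these values.

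The effect of Ezh2 KO differed between the lines of set 1 at Twist2 (adjusted p 0.000631), Lin28b (0.00125) and Igf2bp3 (0.0123), by a test of the difference itself. Of 100 splits of the libraries within lines 1, the real one, gave as many genes, with 3 against at most 2 in the others. The same splits gave 68 genes for the 3 lines together and at most 0 in the others, 1 of 100 as many. For Gfi1 OE, 1 of 100 splits gave as many genes as the real 4187, and the highest other gave 972. For the libraries labelled WT GNP Myc Gfi1 against Gfi1 OE, 1 of 100 gave as many as the real 8413, and the highest other gave 0. For the 3 lines together and for Gfi1 OE, no other split drawn reached the real count. Splits within lines remove the effect of Ezh2 KO itself. They therefore cannot decide whether that effect differs between lines, with 3 genes against 2. The libraries labelled WT GNP Myc Gfi1 and Gfi1 OE differ by genotype and origin in their labels, so that lower counts in mixed splits tell nothing about the cause. Within lines the 10 splits are too few for a share under 0.05: line 19251 gave 48 against at most 0 in the others, line 19554 89 against at most 2, and line 19568 5 against at most 0, with 1 split, the real one, reaching the count in each.

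The libraries labelled WT GNP Myc Gfi1 held 0.232 to 0.83 CPM of Gfi1, against 107 to 592 in Gfi1 OE. A Gfi1 construct that is not counted as Gfi1 is argued against, if its effect is like that in line 19251: the genes that rose over 4-fold with Gfi1 OE had a median log2 difference of -0.0752 (SD 0.944, 348 genes) from Ezh2 KO of set 2, with 44 of them called higher and 41 lower. Cd79a, which rose with Gfi1 OE, went with a construct, at 19.8 ± 1.77 CPM (SD, n = 4) against 5 ± 0.203 (n = 3) in that knockout. Tumors of line 19568 would lie nearest to that line at genes private to it, as the 4 libraries did at 95.7% of 163 genes. For the other lines they did so at 0 of 5 and 0 of 19. These genes are private by expression, with 142 of the 163 higher in line 19568. In Cas9 of set 1 that line held 321 ± 35.9 CPM of Gli1, against 1.49 ± 0.95 and 8.81 ± 5.85 in lines 19251 and 19554 (n = 3 each). A tumor of another origin in a similar state could lie nearest as well, and the test cannot tell these apart. A test on genes silent in line 19568 alone found 0 such genes, with 10 needed, and decided nothing. Ezh2 measured 46.5 to 53.1 CPM in the 4 libraries, against 46.8 to 55.7 in Ezh2 KO of set 2 and 91.9 and 93.5 in Cas9 replicates 2 and 3 of set 2. Gata4 measured 4.24 to 4.94 CPM, against 6.62 to 7.67 in that knockout and 0 and 0.102 in those Cas9 replicates. Cd74 went the other way, at 116 to 349 CPM against 25.1 to 28.9 in that knockout. Whether the 4 libraries are Ezh2 KO tumors of line 19568 was not tested. No biological explanation was tested, and a difference of genotype stays open.

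The library labelled Cas9 set 2 replicate 1 was in no comparison and held 5130 CPM of Ezh2, against 91.9 and 93.5 in the other Cas9 libraries. Its labels may be crossed with those of rescue replicate 3: over 14437 genes its mean correlation was higher with the rescue than with Cas9 by 1.1, and that of the library labelled rescue replicate 3 was higher with Cas9 by 1.16. An Ezh2 construct in a Cas9 tumor is argued against, if its effect is like that in the Ezh2 OE libraries, which are such tumors with 1800 to 2530 CPM of Ezh2: the mean correlation with the rescue minus that with Cas9 was 1.63 higher in this library than in the highest of the 3 Ezh2 OE libraries, whose range was 0.209. A first measure had not decided this, with the 61 genes raised by Ezh2 KO in set 1 at 0.764 above the highest other Cas9 library on a log2 scale, between the bounds of 0 and 1 set for it. No biological explanation was tested.

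MHC class II genes were lower with Ezh2 KO in set 2 (median -3.76, 8 of 9 called) and higher in the rescue (3.1, SD 1.46, 8 of 9 called), on a list written after the values were seen. A change in the amount of RNA from microglia and macrophages as the whole cause is argued against, if these cells kept their own level of MHC class II. Their list had a median of 0.762 in the rescue (SD 0.255). Its markers moved the same way as the MHC class II genes, with 15 of 15 positive in the rescue and 14 negative with the knockout. A changed level within such cells was not tested and stays open. RNA from lymphocytes stays open, with 1 of its markers tested, at 0.663 in the rescue and 1.65 with the knockout. With the knockout that marker moved against the MHC class II genes, and the hosts were immunodeficient per the labels, but 1 marker cannot decide this. An effect of the Ezh2 arm is in line with the median of -3.18 (SD 1.76, 9 of 11 negative, 0 called by edgeR) with Ezh2 KO in line 19568 of set 1. Line 19554 gave 0.601. Line 19251 gave -2.27, or 2.73 without Cas9 replicate 3, which held 363 CPM of H2-Aa against 1.85 and 3.66 in the other 2 Cas9 libraries. The difference between lines was not tested for this list.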

How the results depend on the processing

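The refits without doubted libraries, and the rescue medians over genes chosen without these libraries or in the 6 libraries of line 19568 alone, and the medians of gene lists without single libraries, were chosen only after seeing the data.

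Of 120 values under other settings, single-library refits apart, 71 kept their direction, with counts within 1.5 times and tests on the same side of the threshold, 48 counts moved by over 1.5 times and 1 test passed the threshold. Medians were compared by direction and spread alone, so that a rescue median of -0.27 is among the 71. The cause was not tested except where fewer libraries or genes entered. Of 140 values of single genes 132 kept their direction and side of the threshold, 1 became weaker, 2 stronger and 5 changed sign, all at genes that were not called: Ezh2 in line 19554 without the low-count filter (-0.0853), and Gfi1 in the rescue against the knockout with RLE size factors (-0.00317), DESeq2 (-0.00258), limma-voom (-0.05) and no filter (-0.019). Gfi1 with Ezh2 KO over 3 lines gave 2.61 with limma-voom (adjusted p 0.0484), against an adjusted p of 0.0881 to 0.969 under the other settings and a range of 1.6 to 2.37 without single libraries.

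With DESeq2 the counts were 289 over 3 lines, 842, 556 and 76 in lines 19251, 19554 and 19568 of set 1, 269 for the difference between lines, 1058 for the rescue against the knockout and 2337 against Cas9. On simulated data 20.7% to 47.1% of DESeq2's calls were genes without a change in the comparisons that held changes. The simulated counts took their spread from edgeR's estimates, in a single run per set of libraries, and so were not neutral between the tools. Where the simulation held none, DESeq2 called 27 genes for the difference between lines, 12 for Ezh2 OE and 19 for the rescue against Cas9, and edgeR and limma-voom 0. With limma-voom they were 131, 93, 176 and 44, and 6 for the difference between lines. Without a low-count filter they were 104 over 3 lines, 0 in line 19568 of set 1, and in set 2 2988 for Ezh2 KO, 146 for Ezh2 OE, 1761 for the rescue and 2833 for the rescue against Cas9. A minimum of 1 CPM gave 40 over 3 lines.

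Over 3 lines edgeR called 29 genes with no term for line, 45 with a replicate block, 17 without line 19554, and 0 with counts summed per line and arm, where fewer samples entered. The 6 libraries of the line alone gave 0 genes in line 19251, 29 in line 19554 and 179 in line 19568. A replicate block on them gave 0, 4 and 250, and libraries with the same replicate number had an r over 0.1 in all 3 pairs only in line 19568 of set 1 (0.21, 0.45 and 0.16), where pairs with other numbers reached 0.29. In set 2 a replicate block gave 887 for Ezh2 KO, 79 for the rescue and 538 for the rescue against Cas9.

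With all 12 libraries of set 2 as labelled the counts were 171 for Ezh2 KO, 0 for Ezh2 OE, 69 for the rescue and 0 for the rescue against Cas9, and with the 2 groups crossed they were 2914, 2, 1220 and 3809. Without the library whose description names another arm the rescue gave 21 and the rescue against Cas9 404. Leaving out doubted libraries gave 3 in line 19568 of set 1, 9 for the difference between lines, 232 for Ezh2 KO in set 2, 121 for the rescue and 116 for the rescue against Cas9. Host marker lists as covariates gave 2214 for Gfi1 OE.

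Without single libraries the counts ranged from 51 to 215 over 3 lines, 26 to 375, 29 to 400 and 0 to 20 in lines 19251, 19554 and 19568, 2 to 20 for the difference between lines, 237 to 2347 for Ezh2 KO in set 2, 1 to 1 for Ezh2 OE, 21 to 704 for the rescue, 113 to 2134 for the rescue against Cas9, 3462 to 5738 for Gfi1 OE and 6961 to 11221 for the libraries labelled WT GNP Myc Gfi1. The rescue median of the 5 genes ranged from -2.58 to -2.1, and was -2.77 and -2.5 with the 12 libraries as labelled and crossed, -2.72 over the 3 genes called without doubted libraries, -1.16 over the 61 genes of the 3 lines and -0.27 over the 140 genes raised in the 6 libraries of line 19568 alone. Spearman's rho of Ezh2 KO and Gfi1 OE ranged from -0.11 to 0.053 (jackknife SE 0.14). Without single libraries the median log2 change ranged from -0.0814 to 0.257 for cell cycle genes and -1.17 to 0.359 for interferon and MHC class I genes over 3 lines, -4.37 to 2.73 for MHC class II genes in line 19251, -2.2 to 0.314 for pan-neuronal genes with Ezh2 KO in set 2 and -2.63 to 0 for Hox genes with Ezh2 OE. An arm left with 1 library was assumed to vary like the other groups.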

Other observations

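The library-wide correlations and levels given here were computed only after the data were seen and serve no comparison.

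Over 15242 genes, 33 of 48 libraries had their nearest library in their own group. The library labelled 19251 Cas9 set 1 replicate 1 held 9.91 CPM of Myc, 7.38 of Trp53, 0.265 of Cdkn2a, 456 of the myelin gene Mbp, 52.7 of Cdkn1a, 520 of Xist and 0.0378 of Ddx3y (13.5 and 66.1, and 30.8 and 84.9, in the other 2 Cas9 libraries of the line), with 0.0577% of its counts on histone genes. These values argue against tumor RNA of line 19251 as the main content of that library. Counts on 2 satellite-like genes made up 10.1% and 7.33% in 19554 Ezh2 KO replicates 1 and 3. They made up 7.49% in 19568 Cas9 set 2 replicate 3 and 4.58% in Ezh2 OE replicate 2.

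The libraries labelled WT GNP Myc Gfi1 held 435 to 498 CPM of Gli1, 828 to 972 of Ptch1 and 4.24 to 4.94 of Gata4, and Gli1 lay between 282 and 353 CPM in the Cas9 libraries of line 19568 in set 1. They differed from Ezh2 KO of set 2 at 4106 of 16164 genes, 2071 higher and 2035 lower (6112 at an unadjusted p under 0.05), in edgeR.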
